A study of Mus musculus with 4 samples.

How the data were processed

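RNA was sequenced from 4 libraries of 100 endothelial cells each, sorted by flow cytometry from mouse retinas at postnatal day 16, with 2 libraries of each genotype. Per the labels' protocols, cells were lysed in a guanidine solution, cDNA was amplified with the SMART-Seq v4 Ultra Low Input kit, sheared by sonication and made into libraries with a NuGEN Ovation kit, and sequenced in pairs of 150-base reads on a NextSeq 500. This protocol does not mark strand. Per the submitters' processing notes, the tools were Trimmomatic 0.36 (read trimming), HISAT2 2.1.0 (alignment) and StringTie 1.3.3 (transcript quantification), with genome build mm10; the settings and the annotation release are not given in the sources used here.

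The deposited table holds FPKM per gene (fragments per kilobase of transcript, scaled to the library total), as made by the authors, for 54446 genes; its header names no unit, which was read from the values and from the tools. Of the gene identifiers, 53229 carry the same version in GENCODE M21, and all 53229 have the same transcription start there. Gene spans are given for mm10 from GENCODE M21 where the versioned identifier matched. FPKM divides by the library total, so a large change in a few genes would shift all others; no count test was run, since FPKM are not counts. FPKM are also split by the quantifier between near-identical transcripts, which makes pseudogenes and their parents uncertain.

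Depth was estimated from low values. In genes with 1 annotated transcript longer than 600 bases, FPKM times length fell on a ladder, with 19.8% to 26.6% of values under 400 within 0.02 of a step from a whole step, against 4% at random. If a step is 1 fragment, the depths are 20.5, 11.2, 21.9 and 16.7 M fragments for control 1, control 2, Zeb1-CKO 1 and Zeb1-CKO 2. Control 2 is thus the shallowest, at 0.510 of the deepest library, and its low values are the least precise. Reads were amplified and carry no molecular identifiers, so the depth overstates the number of independent molecules. None of 17 housekeeping genes was at 0 in any library.

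Each column was matched to its sample by name, and all were matched. The main test was limma 3.58.1 (R 4.3.3) with an intensity trend on log2(FPKM + 1), with genotype as the only term, for the 13651 genes with a mean of at least 1 FPKM over the 4 libraries and Benjamini-Hochberg adjusted p under 0.05. The groups compared were control and Zeb1-CKO, and intervals between them rest on 2 libraries each; nothing states that the libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical. On simulated data with 13651 genes, the same test recovered 14% of 100 genes with a log2 change of 1 and 84% of 100 genes with a log2 change of 2, with 7 false calls among 105, and made 0 calls when no gene was changed. The simulated genes varied independently of each other, with a spread drawn from the real fit. These false calls thus do not measure the error rate in the real libraries.

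Gene lists were 32 sets written before the data were examined, covering vascular identity and signalling, barrier, matrix, metabolism, inflammation, epithelial genes and other retinal cell types. The 30 lists with at least 5 fitted genes were tested with camera at a preset correlation of 0.01, adjusted over lists. Camera with an estimated correlation and fry were alternatives. With an estimated correlation, the adjustment gave many lists the same adjusted p of 0.432. Their unadjusted camera p differed, from 0.0189 for the epithelial list to 0.187 for glycolysis and hypoxia. Summed FPKM of marker lists are given per library or as mean ± SD. The genes named are Zeb1 and Zeb2; up to 10 higher and 10 lower genes with the largest log2 fold change among called genes whose libraries do not overlap, with a mean of at least 5 FPKM in the higher genotype, leaving out predicted genes, pseudogenes and mitochondrial genes; up to 4 called members of each list by smallest p, or the 2 most abundant where none passed; and the 2 most abundant markers of other cell types. Cldn7, Pkp3, Grhl2, Marveld2, C1qb and Hey1 were added after their values were seen. Some genes that the rule takes are not reported here.

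Transcripts of called and named genes were compared with all others by BLAST 2.17.0, and a fitted gene with at least 95% identity over at least 80% of either transcript, of at least 200 bases, was taken as a near-identical copy. Alternatives were the replicate number as a block, each library left out, other pseudocounts, filters, scalings and variance models, other thresholds, and other list tests; alternatives meant for counts were not run. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.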

Results

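Gene expression was measured by RNA sequencing in endothelial cells, the cells that line blood vessels, sorted by flow cytometry from the retinas of C57BL/6 mice at postnatal day 16. Each library was made from 100 sorted cells. There were 2 libraries from control mice and 2 from mice labelled Zeb1-CKO, in which Zeb1, a zinc-finger transcriptional repressor of epithelial genes, is named as conditionally knocked out in the titles and as knocked down in the genotype field. The comparison asks how expression in retinal endothelial cells differs when Zeb1 is targeted. The deposited values are FPKM for 54446 genes, with library sums of 294276 and 293840 in the controls and 283814 and 291486 in the Zeb1-CKO libraries. From the steps between low values, the estimated depths were 20.5 and 11.2 M fragments in control libraries 1 and 2, and 21.9 and 16.7 M in Zeb1-CKO libraries 1 and 2. For a transcript of 2000 bases, 1 such step is worth 0.0228 to 0.0448 FPKM. Across the 13651 fitted genes, Pearson's r of log2 values was 0.967 between the controls, 0.972 between the Zeb1-CKO libraries and 0.932 to 0.941 between genotypes; genes are not independent replicates in these values.

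Zeb1, on chromosome 18 with its transcription start at 5591860 in mm10, was measured at 10.7 and 11.1 FPKM in the controls and at 8.66 and 7.07 FPKM in the Zeb1-CKO libraries. Its mean was 10.9 ± 0.299 FPKM (SD, n = 2) in controls and 7.87 ± 1.13 FPKM (SD, n = 2) in Zeb1-CKO cells. Both Zeb1-CKO libraries were lower than both controls, but the difference of -0.43 on the log2 scale (SE 0.15) did not pass limma's threshold, with an adjusted p of 0.235. A value per gene cannot separate the deleted part of Zeb1 from the rest of its transcript, so it is a weak check of the labels. Its paralog Zeb2 was measured at 3.75 ± 0.752 FPKM (SD, n = 2) in controls and 3.08 ± 0.457 in Zeb1-CKO cells, with limma's adjusted p at 0.615.

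In cells sorted from Zeb1-CKO retinas, genes of epithelial junctions and epithelial surface proteins rose strongly from low levels, while the chemokines Ccl3 and Ccl4 and the Wnt pathway gene Nkd1 fell. Cldn6, which encodes a tight-junction claudin (chromosome 17, 23679249 to 23682446), rose from 0.881 ± 0.957 FPKM to 334 ± 16.5 FPKM (SD, n = 2 per genotype), a log2 fold change of 7.58 (SE 0.35). Epcam, an epithelial adhesion molecule, was at 0.0477 FPKM in control 1, was listed at 0 in control 2, and reached 58.5 and 57.1 FPKM in the Zeb1-CKO libraries. Cdh1, which encodes E-cadherin (chromosome 8, 106603351 to 106670246), rose from 0.0887 ± 0.0947 to 22.4 ± 0.0912 FPKM, a log2 fold change of 4.43 (SE 0.16). In all, 304 genes were higher and 123 were lower in Zeb1-CKO than in control cells among 13651 fitted genes, by limma on log2(FPKM + 1) with Benjamini-Hochberg adjusted p under 0.05. The libraries of the 2 genotypes did not overlap for these 427 genes; of all fitted genes, 49.4% did not overlap, against 33.3% by chance. With 2 libraries per genotype the counts were fragile. A fit without 1 library has fewer samples, so a call can end there while its fold change stays similar. Without Zeb1-CKO replicate 1, 51 genes were higher and 15 lower, of which 48 and 13 were also called with all 4 libraries. Without Zeb1-CKO replicate 2, 48 genes were higher and 24 lower, of which 47 and 12 were shared. Without control replicate 1 or 2, both counts also fell. Most genes called higher with all 4 libraries were still called in these fits, while most of those called lower were not. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes.

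**Figure D1:**
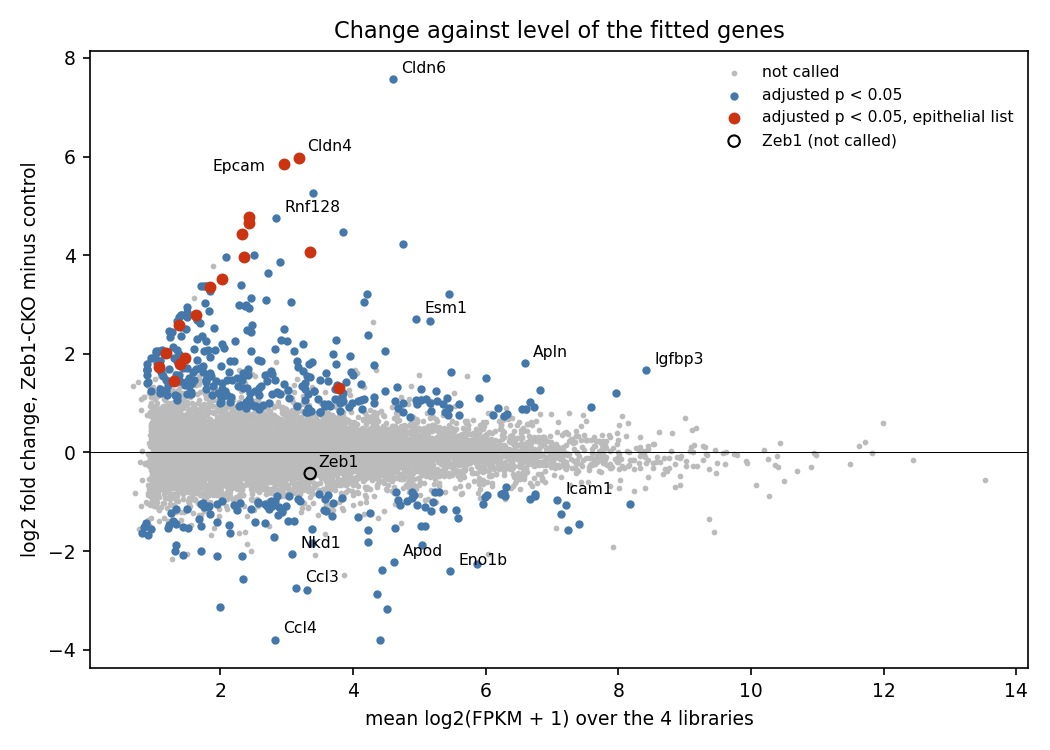
Each point is a fitted gene, with its mean log2(FPKM + 1) over the 4 libraries on the x axis and its log2 fold change, Zeb1-CKO minus control, on the y axis; colored points passed an adjusted p of 0.05. Cldn6 has a log2 fold change of 7.58, the 17 red members of the epithelial list all lie above 0, and Zeb1 lies at -0.43 among genes that did not pass.

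The other genes with the largest rises under the naming rule were Cldn4 (log2 fold change 5.98), Ap1m2 (4.77), Rnf128 (4.75), Spint1 (4.66), Spint2 (4.06), Wfdc2 (4.01) and Krt18 (3.97), next to Epcam at 5.84, with limma's adjusted p between 0.000320 for Epcam and 0.00280 for Wfdc2. Ap1m2 encodes a subunit of the epithelial clathrin adaptor AP-1B, Spint1 and Spint2 encode Kunitz-type inhibitors of membrane serine proteases, Krt18 encodes a keratin of simple epithelia, and Rnf128 encodes an E3 ubiquitin ligase. Rnf128 was at 0.385 ± 0.0444 FPKM in controls and 36.2 ± 0.869 FPKM in Zeb1-CKO cells (SD, n = 2 per genotype). Each of these 10 rises was also called without any 1 of the 4 libraries, with adjusted p up to 0.0437 for Wfdc2.

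The epithelial list holds genes known to be repressed by ZEB1 or restricted to epithelia, and none of its members stands in another list. Of its 27 members, 17 reached the mean of 1 FPKM needed to be fitted and all 17 rose, also when adjusted over the list alone, with a median log2 fold change of 3.35. Since that mean includes the Zeb1-CKO libraries, a member silent in controls is fitted only if it is higher in Zeb1-CKO cells; the other 10 members stayed below it. Beside the genes named above, the claudin gene Cldn7 reached 12.7 and 12.9 FPKM from 0.231 and 0.168, the desmosomal plaque gene Pkp3 reached 10.7 and 10.2 from 0.249 and 0.0115, and the transcription factor gene Grhl2 reached 2.82 and 2.88 from 0.161 and 0.157. Marveld2, a tricellular tight-junction gene already present in controls at 8.82 and 6.80 FPKM, was at 20.8 FPKM in each Zeb1-CKO library. The camera test of the list gave an adjusted p of 5.26e-29, which rests on the members that passed the filter on the mean. Over the alternatives the adjusted p ranged from 2.34e-33 to 0.432, the latter with an estimated correlation between genes (unadjusted p of 0.0189). Without Zeb1-CKO replicate 1 or without replicate 2, 10 members were called.

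**Figure D2:**
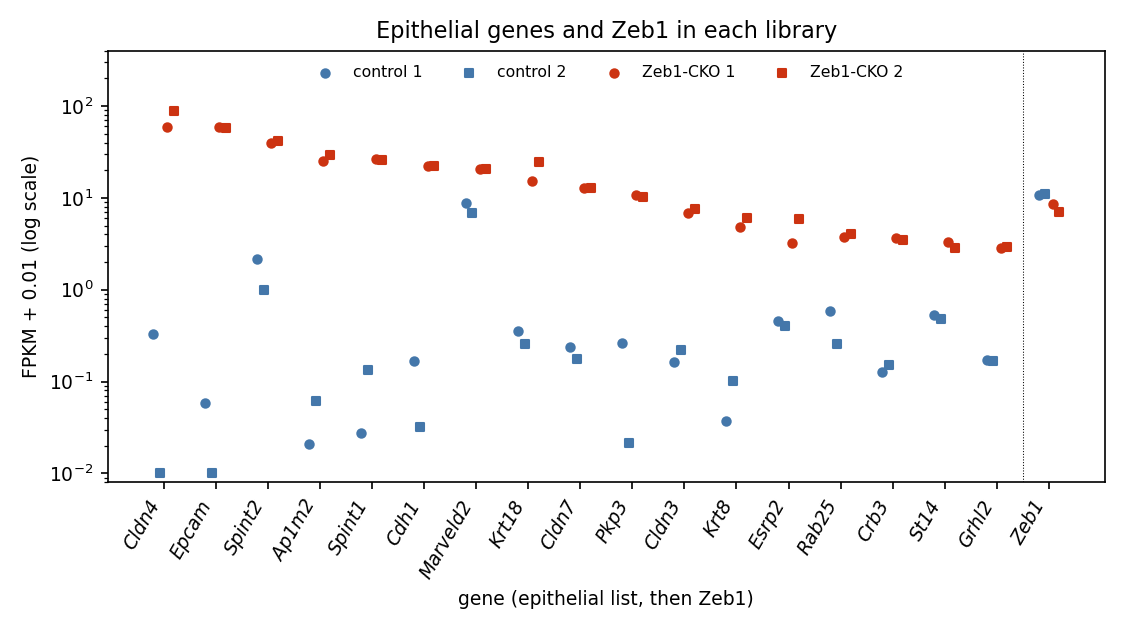
FPKM plus 0.01 on a log axis for the 17 fitted members of the epithelial list and for Zeb1, with 1 point per library (blue, control; red, Zeb1-CKO; circles, replicate 1; squares, replicate 2). Every red point of the list lies above both blue points of its gene, and Zeb1 lies between 7.07 and 11.1 FPKM in all 4 libraries.

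Among the genes that fell, Ccl4 and Ccl3, which encode chemokines made mainly by myeloid cells, had log2 fold changes of -3.79 (SE 0.37) and -2.75 (SE 0.20). Ccl4 was at 18.6 and 34.4 FPKM in the controls and at 1.48 and 0.452 in the Zeb1-CKO libraries, and Ccl3 went from 22.1 ± 3.86 to 2.45 ± 0.576 FPKM (SD, n = 2 per genotype). The call of Ccl4 ended without Zeb1-CKO replicate 2 (adjusted p = 0.0550). Microglial markers were lower as a list beside them, with a median log2 fold change of -1.20 over 11 fitted members and a camera adjusted p of 0.00406. The adjusted p ranged from 3.34e-08 to 0.581 over the alternatives, the latter with an estimated correlation. None of the 11 passed limma's threshold over all genes, 7 had an unadjusted p under 0.05, and 5 fell and 1 rose adjusted over the list alone. Lyz2 was at 9.27 and 18.3 FPKM in controls and 14.1 and 1.48 in Zeb1-CKO libraries, and C1qb at 5.03 and 15.7 against 2.47 and 1.22.

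Apod, which encodes the lipocalin apolipoprotein D, fell 4.97-fold from 52.2 ± 2.61 to 10.5 ± 1.96 FPKM (SD, n = 2 per genotype). Nkd1, a Wnt-induced antagonist of Wnt signalling, fell 5.15-fold from 16.3 ± 1.11 to 3.17 ± 0.481 FPKM. The other genes that fell under the naming rule were Eno1b (log2 fold change of -2.41), Tnfaip2 (-1.99), the noncoding locus Gt(ROSA)26Sor (-1.88), C1d (-1.84), Wfdc1 (-1.81) and Cd83 (-1.72). The call of Wfdc1 ended without Zeb1-CKO replicate 1 (adjusted p = 0.05001). Those of Tnfaip2, C1d, Cd83 and Gt(ROSA)26Sor ended without either, with adjusted p between 0.0553 and 0.151. Eno1b is uncertain, since its transcript is 99.5% identical to that of Eno1, which was at 82.8 and 77.4 FPKM in controls and 118 and 123 FPKM in Zeb1-CKO libraries. Gt(ROSA)26Sor shares 145 of its 1695 exon bases with Thumpd3 on the opposite strand, and the libraries do not mark strand. Thumpd3 had means of 5.31 FPKM in controls and 3.48 in Zeb1-CKO cells, against 64.5 and 16.2 for Gt(ROSA)26Sor. These values argue against reads of Thumpd3 as the main source of the fall.

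Genes of sprouting tip cells were measured with a list of 16, all fitted, of which 4 rose, 1 fell and 11 did not pass. Esm1, which encodes the endothelial proteoglycan endocan, rose from 11.2 ± 2.23 to 78.6 ± 17.5 FPKM (SD, n = 2 per genotype). Apln, which encodes the peptide apelin, rose 3.55-fold from 50.6 ± 3.66 to 180 ± 12.7 FPKM. Igfbp3 rose from 192 ± 39.9 to 613 ± 97.2 FPKM, and the potassium channel subunit gene Kcne3 from 12.1 and 7.89 FPKM to 31.2 and 41.5 FPKM. The netrin receptor gene Unc5b fell from 10.8 and 13.1 FPKM to 5.44 and 5.66 FPKM. Adjusted over the list alone, 6 members rose and 1 fell. Camera gave the list a rise with an adjusted p of 0.0122. Over the alternatives the adjusted p ranged from 0.00110 to 0.432, the latter with an estimated correlation, and it was 0.0727 without Zeb1-CKO replicate 1. The calls of Esm1 and Apln were kept without any 1 library. Those of Igfbp3 and Kcne3 ended without Zeb1-CKO replicate 1 or 2. Their log2 fold changes there were 1.51 and 1.84 for Igfbp3 and 1.98 and 1.57 for Kcne3. That of Unc5b ended without any 1 library, at log2 fold changes of -1.11 to -0.847.

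Cell-cycle and glycolytic genes mostly had higher values in Zeb1-CKO cells, by less than the per-gene threshold for nearly all members. Of 27 cell-cycle genes, 26 had a positive log2 fold change, with a median of 0.46. Only Mcm3, a subunit of the replicative helicase, rose, from 8.09 ± 0.0695 to 16.5 ± 0.139 FPKM (SD, n = 2 per genotype), and 5 rose adjusted over the list alone. Of 23 fitted genes of glycolysis and the hypoxia response, 22 had a positive log2 fold change, with a median of 0.41. Only Egln3, an oxygen-dependent prolyl hydroxylase gene, rose, from 1.44 ± 0.289 to 4.48 ± 0.225 FPKM, and 9 rose adjusted over the list alone. Camera's adjusted p was 4.70e-07 for the cell-cycle list (4.42e-12 to 0.432 over the alternatives) and 7.72e-06 for glycolysis and hypoxia (1.13e-08 to 0.432), with the adjusted p of 0.432 in both from an estimated correlation. The calls of Mcm3 and Egln3 both ended without any 1 library. Their log2 fold changes there ranged from 0.934 to 0.950 and from 1.05 to 1.29, respectively.

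Of 15 fitted genes of the Wnt and norrin pathway, Nkd1 and Apcdd1 fell and 13 did not pass. The same 2 fell adjusted over the list alone. Apcdd1, a membrane inhibitor of Wnt signalling, fell from 106 ± 7.60 to 56.6 ± 0.109 FPKM (SD, n = 2 per genotype). Camera gave this list a fall with an adjusted p of 0.0122. The adjusted p ranged from 0.00582 to 0.432 over the alternatives, the latter with an estimated correlation, and it was 0.0602 without control replicate 2. Among 19 genes of the blood-retina barrier, the thyroid hormone transporter gene Slco1c1 fell from 48.9 ± 0.962 to 27.8 ± 1.33 FPKM, the caveolar gene Cav1 rose from 4.27 ± 0.325 to 11.6 ± 0.0217 FPKM, and 17 did not pass. Of these 19, 2 rose and 2 fell adjusted over the list alone, and the list's camera adjusted p was 0.346. The calls of Apcdd1 and Slco1c1 ended without any 1 library, at log2 fold changes of -0.960 to -0.814 and -0.842 to -0.748. That of Cav1 ended without Zeb1-CKO replicate 1 or 2, at 1.26 in each fit.

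Of 19 inflammatory and adhesion genes, 16 had a negative log2 fold change. The leukocyte adhesion gene Icam1 fell 1.95-fold from 187 ± 5.47 to 95.6 ± 1.04 FPKM, the cytokine gene Il6 fell 2.81-fold from 55.9 ± 6.79 to 19.9 ± 6.92 FPKM, and Lcn2, the siderophore-binding lipocalin gene, rose from 0.722 ± 0.0396 to 6.24 ± 0.619 FPKM (SD, n = 2 per genotype). Adjusted over the list alone, 2 rose and 4 fell. Camera's adjusted p for a fall was 0.00781. Over the alternatives the adjusted p ranged from 9.29e-05 to 0.432, the latter with an estimated correlation. Microglial markers were lower beside this list, with a negative log2 fold change in 10 of 11 fitted members, a median of -1.20 and a camera adjusted p of 0.00406 (0.581 as adjusted p with an estimated correlation). The calls of Icam1 and Il6 ended without any 1 library, at log2 fold changes of -0.989 to -0.930 and -1.83 to -1.14. That of Lcn2 ended without Zeb1-CKO replicate 1 or 2, at 1.98 and 2.16.

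Of 16 fitted mesenchymal genes, Tagln, an actin-binding gene of smooth muscle, fell from 15.7 ± 1.27 to 8.21 ± 0.508 FPKM (SD, n = 2 per genotype), and 5 fell and 1 rose adjusted over the list alone. Camera's adjusted p for a fall was 0.00381. The adjusted p ranged from 0.00110 to 0.432 over the alternatives, the latter with an estimated correlation. Tagln stands also in the smooth-muscle list, which was lower in Zeb1-CKO cells. Its summed markers were at 584 and 437 FPKM in controls and 263 and 339 FPKM in Zeb1-CKO libraries, with Myl9 at 337 ± 76.6 and 202 ± 41.6 FPKM and Acta2 at 109 ± 23.3 and 56.3 ± 13.4 FPKM. In that list 1 of 7 fitted genes fell, or 5 adjusted over the list alone, and its camera adjusted p was 0.000216 (1.79e-05 to 0.432 over the alternatives, with the adjusted p of 0.432 from an estimated correlation). Pericyte markers were also lower, in 13 of 14 members (camera adjusted p of 0.00213, and an adjusted p of 0.432 with an estimated correlation). The call of Tagln ended without any 1 library, at log2 fold changes of -0.932 to -0.777. Tagln is also uncertain because it shares 1241 of its 1988 exon bases with the antisense gene Gm48529, and 108 with Pcsk7 on the opposite strand, in libraries that do not mark strand.

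None of the 18 pan-endothelial genes passed limma's threshold, and 5 had an unadjusted p under 0.05. Cldn5, the main endothelial claudin, was at 3060 ± 520.4 FPKM in controls and 3317 ± 260.0 FPKM in Zeb1-CKO cells (SD, n = 2 per genotype), and Esam was at 329.6 ± 13.9 and 313 ± 7.56 FPKM. The list's camera adjusted p was 0.859. Of 13 arterial genes, Unc5b fell (2 rose and 3 fell adjusted over the list alone; list 0.368, and 0.0467 to 0.999 over the alternatives). None of 11 venous genes passed (5 at an unadjusted p under 0.05, 2 rose and 2 fell adjusted over the list alone; list 0.0998, and 0.0265 to 0.432 over the alternatives), with Slc38a5 at 369.7 and 313.6 FPKM in controls and 273 and 316 FPKM in Zeb1-CKO libraries. Of 18 fitted angiogenic ligands and receptors, Pgf, which encodes placental growth factor, rose from 2.22 ± 0.0750 to 7.04 ± 1.31 FPKM, the 1 rise adjusted over the list alone (list 0.309). Of 17 genes of p53 and apoptosis, Pmaip1 rose from 39.9 ± 4.17 to 87.3 ± 18.2 FPKM and the cell-cycle inhibitor gene Cdkn1a fell from 143 ± 19.5 to 79.2 ± 2.99 FPKM (2 rose and 3 fell adjusted over the list alone; list 0.497). The calls of Pgf, Pmaip1, Cdkn1a and Unc5b each ended without any 1 library. Their log2 fold changes there were 1.145 to 1.48, 0.8885 to 1.31, -0.981 to -0.704 and -1.11 to -0.847, respectively.

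No gene passed limma's threshold in 6 further lists. Of 14 Notch pathway genes, 2 had an unadjusted p under 0.05 and 1 rose adjusted over the list alone, Hey1, at 18.7 and 41.7 FPKM (log2 fold change of 1.09, adjusted p of 0.0530 over all genes). Abundant members were Dll4 at 109 ± 16.7 and 127 ± 7.44 FPKM and Hes1 at 91.4 ± 0.0712 and 87.7 ± 13.8 FPKM (SD, n = 2 per genotype; camera adjusted p of 0.959). Their median log2 fold change was -0.02, the mean 0.06 and camera's direction down. Of 14 basement-membrane genes, 2 had an unadjusted p under 0.05, with Sparc at 1444 ± 46.5 and 1210 ± 46.0 FPKM (0.901). The median was -0.01, the mean 0.00262 and camera's direction down. Of 23 fitted TGF-β and BMP pathway genes, 5 had an unadjusted p under 0.05, with Id3 at 315 ± 29.3 and 217 ± 39.4 FPKM and Eng at 229.8 ± 8.99 and 202 ± 0.230 FPKM (0.0736, and 0.0328 to 0.519 over the alternatives). Of 17 fitted interferon response genes, 3 had an unadjusted p under 0.05, with Ifitm3 at 623 ± 140.7 and 395 ± 92.2 FPKM and Bst2 at 23.6 ± 6.65 and 35.5 ± 4.97 FPKM (0.859). Of 25 oxidative phosphorylation genes none had an unadjusted p under 0.05, with Cox6a1 at 422 ± 39.7 and 375 ± 84.8 FPKM. The camera adjusted p was 0.231, and 0.00729 for a fall without Zeb1-CKO replicate 2. Of 17 fitted secreted matrix-remodelling genes 9 had an unadjusted p under 0.05, and 5 fell and 1 rose adjusted over the list alone, with Cyr61 at 608 ± 28.7 and 661 ± 15.0 FPKM and Adamts1 at 221 ± 19.7 and 203 ± 23.9 FPKM. Camera's adjusted p for a fall of this list was 0.0122. Over the alternatives the adjusted p ranged from 0.00470 to 0.470, the latter with an estimated correlation, and it was 0.0727 without control replicate 2 and 0.0703 without Zeb1-CKO replicate 2. Pericyte and smooth-muscle markers were lower beside this list, with negative log2 fold changes in 13 of 14 and 7 of 7 fitted members and camera adjusted p of 0.00213 and 0.000216 (0.432 as adjusted p with an estimated correlation for both). Dll4 and Eng share 214 and 61 exon bases with genes on the opposite strand.

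**Figure D3:**
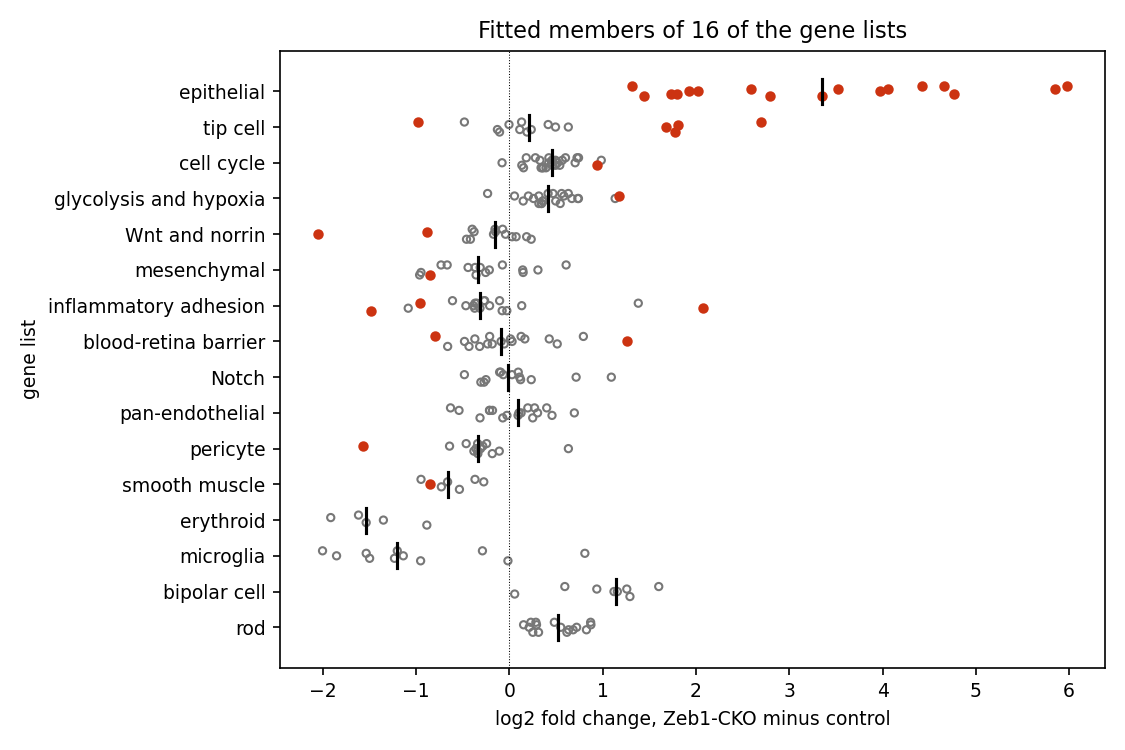
Each point is a fitted member of a gene list and its x position is the log2 fold change, Zeb1-CKO minus control; red points passed an adjusted p of 0.05, open points did not, and black bars are list medians. The epithelial list has its median at 3.35 and the pan-endothelial list at 0.10.

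Markers of other cell types were present in the sorted cells, and some differed between the genotypes. Pericyte markers summed to 2773 and 2259 FPKM in controls and 1898 and 2135 in Zeb1-CKO libraries, with camera's adjusted p for a fall at 0.00213 (0.000101 to 0.432 over the alternatives, with the adjusted p of 0.432 from an estimated correlation). Of the 14 pericyte genes, Ifitm1 fell, 2 fell adjusted over the list alone, and Rgs5 was at 1510.3 ± 230.1 and 1232 ± 43.2 FPKM (SD, n = 2 per genotype). The call of Ifitm1 ended without Zeb1-CKO replicate 1 or 2 (adjusted p of 0.166 and 0.138). The 7 measured red-cell genes summed to 2730.2 and 3299 FPKM in controls and 746 and 1410 in Zeb1-CKO libraries, with a camera adjusted p for a fall of 0.000109 (1.01e-06 to 0.432 over the alternatives, with the adjusted p of 0.432 from an estimated correlation). None of the 5 fitted red-cell genes passed limma's threshold over all genes, and all 5 fell adjusted over the list alone. Hbb-bs was at 1065 ± 241 and 421 ± 128 FPKM, and Hba-a1 at 1221 ± 11.5 and 427 ± 222 FPKM. The level of Hba-a1 is uncertain because of its near-identical copy Hba-a2. Hba-a2 was lower too (log2 fold change of -1.92), as was the sum of both (-1.70), which argues against reads exchanged between them as the source. Astrocyte markers summed to 114 and 97.7 FPKM in controls and 138 and 204 in Zeb1-CKO libraries, with Gfap at 58.7 ± 2.77 and 103 ± 48.8 FPKM. Camera's adjusted p for a rise was 0.0193 (0.00375 to 0.432 over the alternatives, with the adjusted p of 0.432 from an estimated correlation), and 0.121 without control replicate 2. Bipolar-cell markers summed to 10.5 and 9.40 FPKM in controls and 15.8 and 53.3 in Zeb1-CKO libraries, with Otx2 at 1.75 ± 0.934 and 4.64 ± 3.35 FPKM. Camera's adjusted p for a rise was 0.0122 (1.77e-06 to 0.574 over the alternatives, with the adjusted p of 0.574 from an estimated correlation). No astrocyte or bipolar gene passed limma's threshold, with 2 in each list at an unadjusted p under 0.05; adjusted over the list alone, 2 astrocyte and 0 bipolar genes rose.

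Rod markers summed to 269 and 86.3 FPKM in controls and 206 and 239 in Zeb1-CKO libraries, with Gnb1 at 60.6 ± 4.33 and 97.9 ± 6.01 FPKM (SD, n = 2 per genotype). Gnb1 did not follow the rod sums between the controls, where it was at 63.7 and 57.6 FPKM. The list's camera adjusted p was 0.148, and it was 8.06e-15 for a rise without control replicate 1 and 2.98e-05 for a fall without control replicate 2. Müller glia markers summed to 373 and 397 FPKM in controls and 401 and 390.5 in Zeb1-CKO libraries (camera adjusted p of 0.959). Fibroblast markers summed to 87.3 ± 1.25 and 78.7 ± 0.821 (0.0763, and 0.0460 to 0.432 over the alternatives), and markers of amacrine, ganglion and horizontal cells to 47.1 ± 1.19 and 50.2 ± 16.1 (0.681). Cone markers summed to 16.2 ± 5.46 and 24.0 ± 16.0 FPKM and pigment epithelium markers to 7.36 and 6.64 against 6.52 and 6.23 FPKM, with too few fitted genes for a list test. No member passed limma's threshold in these 6 lists, and at an unadjusted p under 0.05 there were 1 rod, 5 Müller glia, 4 fibroblast, 2 amacrine, ganglion or horizontal cell, 0 cone and 1 pigment epithelium genes. Adjusted over the list alone, 1 rod and 1 pigment epithelium gene rose, 2 Müller glia genes rose and 2 fell, and 1 fibroblast gene rose and 3 fell. Genes induced by tissue dissociation summed to 8335 ± 402 FPKM in controls and 8037 ± 197 in Zeb1-CKO cells (camera adjusted p of 0.204). Of these Klf2, a flow-responsive transcription factor gene, fell from 145 ± 2.12 to 78.1 ± 1.42 FPKM, with 1 rise and 3 falls adjusted over the list alone. Its call ended without any 1 library, at log2 fold changes of -0.902 to -0.865. Mitochondrial genes made up 6.98% to 7.71% of the FPKM sum in the 4 libraries, and ribosomal protein genes 3.84% to 4.82%.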

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

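The settings restricted to protein-coding genes or to genes without a near-identical copy, the list tests under the gene-level settings, and the count over other splits of the libraries were chosen after the data were seen; the others were planned, and those meant for counts were not run. The replicate numbers were not stated to pair libraries, and deviations of same-numbered libraries correlated at -0.118; with the replicate block, 155 genes were higher and 38 lower. The higher and lower counts were 70 and 15 with no filter on low values and 553 and 306 at an adjusted p of 0.1, and 169 genes were higher with a mean FPKM of at least 5; a filter changes how many genes are adjusted together. Leaving out 1 library, where the lone library is assumed to vary like the other genotype, gave 48 to 238 higher and 15 to 64 lower genes, in fits with fewer samples. The number of epithelial genes that rose was 17 under most settings, 15 with the replicate block, 11 with no filter, 10 of 10 fitted with a mean of at least 5 FPKM, and 10 to 15 without 1 library. Of 30 lists, 14 passed with camera, 12 to 16 under the gene-level settings and without 1 library, 2 with fry and 0 with an estimated correlation; the cause was not tested for these. Rod markers reversed without control replicate 2 (adjusted p = 2.98e-05), and without 1 library their adjusted p ranged from 8.06e-15 to 0.217. Zeb1 stayed lower and not called under every setting run, with log2 fold changes from -0.56 to -0.30. Of 39 named genes that were called, 16 stayed called under every setting in which they were fitted, none changed direction, and the others lost the call in at least 1 setting. The other splits of the 4 libraries called at most 2 genes, against 427 for the real split (1 of 3 splits with as many), too few splits for a share under 0.05. Genes below the level of 1 fragment per library cannot be ranked, and control 2 is limited most by depth.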

Other observations

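All genes and tests of this part were chosen after the results were seen. Mmrn1, which encodes multimerin 1, rose from 5.09 ± 0.857 to 55.2 ± 0.676 FPKM, Procr, the endothelial protein C receptor gene, from 5.27 ± 0.449 to 50.7 ± 0.816 FPKM, and Gpihbp1, the capillary anchor of lipoprotein lipase, from 13.2 ± 0.798 to 89.8 ± 17.5 FPKM (SD, n = 2 per genotype; limma's adjusted p of 0.000974, 0.00102 and 0.00267 for Procr, Mmrn1 and Gpihbp1). Slc22a8, an organic anion transporter gene of barrier endothelium, fell from 74.6 ± 3.51 to 29.3 ± 0.626 FPKM, and Selenop, which encodes a plasma selenium carrier, from 416 ± 1.31 to 201 ± 1.06 FPKM. Phgdh, the first enzyme of serine synthesis, rose from 10.3 and 9.68 FPKM to 42.0 and 47.3 FPKM, and Trib3 and Chac1 rose from 2.07 and 2.82 to 13.5 and 13.9 FPKM and from 3.23 and 3.64 to 7.02 and 7.27 FPKM. Other genes of serine synthesis or the ATF4 response did not pass, with log2 fold changes of -0.23 for Psat1, 0.21 for Psph, 0.16 for Shmt2, 0.12 for Mthfd2, 0.97 for Asns, 0.02 for Ddit3, 0.39 for Atf4 and -0.04 for Sesn2. Slc7a11, below the level needed to be fitted, was at 0.839 ± 0.221 FPKM in controls and 0.374 ± 0.0346 FPKM in Zeb1-CKO cells.

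Xist had a log2 fold change of -1.10 (limma's adjusted p of 0.0743) and Y-linked Ddx3y of 0.74 (0.0621), neither of which passed. The other Y-linked genes measured had values in the same direction as Ddx3y, with log2 fold changes of 0.62 for Eif2s3y and 0.26 for Uty that did not pass, and Kdm5d, below the level needed to be fitted, at a mean of 0.567 FPKM in controls and 1.25 FPKM in Zeb1-CKO cells. The labels do not give the sex of the animals. Xist (4.61 to 15.0 FPKM) and Ddx3y (13.3 to 25.1 FPKM) were both measured in all 4 libraries, so no library held RNA of 1 sex only. A different mix of the sexes in the 2 genotypes was not tested as a source of any call. The rises of Epcam (log2 fold change of 5.84) and Cldn6 (7.58) were far larger than these differences, while calls such as Mcm3 (0.94), Icam1 (-0.96) and Klf2 (-0.88) were no larger than that of Xist.

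The rise of the epithelial genes was set against cells of another type and against scaling. Krt5, Krt14 and Krt12 of surface epithelium summed to a mean of 0.0363 FPKM in the Zeb1-CKO libraries, and Rpe65, Rgr and Ttr of pigment epithelium to 0.410 FPKM against 0.557 in controls, far below Epcam at 57.8 FPKM, which argues against either tissue as the source; 17 members rose under both other scalings, which argues against scaling. Cells of a simple epithelium cannot be told apart from the sorted cells themselves by keratins, since Krt8 and Krt18 are themselves among the genes that rose. Krt19 stayed low, at a mean of 0.259 FPKM in the Zeb1-CKO libraries, against 5.41 for Krt8 and 19.8 for Krt18. The purity of the sort was not measured, and pericyte markers summed to 1898 and 2135 FPKM in the Zeb1-CKO libraries. The fitted epithelial members differed between the Zeb1-CKO libraries by a median of 0.02 on the log2 scale, against 0.03 for pan-endothelial genes. The median was -0.24 for microglial, 0.63 for red-cell and 1.296 for bipolar-cell markers. Such evenness cannot tell the source, since summed fibroblast (78.1 and 79.3 FPKM) and Müller glia markers (401 and 390.5 FPKM) were also even. Release of the epithelial genes from repression by Zeb1 is a hypothesis that may account for their rise. The 17 fitted members called higher cannot test it. Most were under 1 FPKM in controls, and so were fitted only because they were higher in Zeb1-CKO cells. Zeb1 itself did not pass the test, and with 2 libraries per genotype release from repression stays a hypothesis.

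The fall of Ccl3 and Ccl4 could come from fewer microglia in the Zeb1-CKO libraries. The fitted microglial markers had a median log2 fold change of -1.20; most are too low in controls for their size to be compared with that of Ccl3 and Ccl4. A lower share of microglia and a change in the cells that remained cannot be told apart here, because the controls themselves differ (C1qb at 5.03 and 15.7 FPKM) and the list's p was 0.368 with an estimated correlation. An effect of genotype on these chemokine genes stays open and was not tested separately.

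Of the 427 called genes, 55 had a near-identical fitted copy, among them 36 of 38 called pseudogenes. Genes sharing exons at 1 locus were not set apart from copies, so the 55 may include some of them. Rpl3-ps1 fell from 127.5 ± 0.337 to 25.9 ± 2.57 FPKM and BC002163, similar to Ndufs5, from 78.4 ± 6.85 to 4.84 ± 1.83 FPKM (SD, n = 2 per genotype). Their copies Rpl3 and Ndufs5 had log2 changes of 0.62 and 0.76, neither of which passed. If reads were exchanged between copies, the most abundant copy could move the other way; it did so in 28 of 55 genes (two-sided exact binomial p = 1.00), so shared reads and real changes cannot be told apart by this test. Tpm3-rs7 rose from 12.8 and 13.8 to 139 and 126 FPKM while Tpm3 had a log2 change of -0.51. DNA carried along with the Zeb1 allele on chromosome 18 was also considered. On this chromosome lie 4 of the 55 (two-sided Fisher's exact p = 0.0558) and 12 of all called genes (p = 0.758 by the same test). The counts are too few to decide, and they cover the whole chromosome rather than the region near Zeb1. Eno1b, 1 of the 4, starts at 48045335, against 5591860 for Zeb1. Sequence differences elsewhere in the genome could not be examined in FPKM.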
